A study of Mus musculus with 2 samples.

How the data were processed

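The study compared heart RNA of WT and MHC403/+ mice by 5′RNA-seq. Per the labels' protocols, RNA was extracted with Trizol, intact polyA RNA was used without fragmenting RNA or cDNA, and libraries were size-selected and linearly amplified. Per the series' design text, biological replicates were pooled, and the number of animals per pool is not given in the sources used here. TopHat 1.0.14 and the mm9 build are named in the submitters' processing notes. The program that counted reads, its use of strand and of reads with several matches, and the read length are not given in the sources used here.

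The data were 1 table of 30385 entries with gene symbol, description, mm9 position, annotated transcript starts and the windows around and downstream of those starts. Per the file headers, the authors deposited read counts per gene for each library, as whole numbers with no normalization. Per the file headers, the authors deposited normalized reads, which on recomputation were RPM, reads scaled to the total over all listed entries, with a largest difference of 4.94e-06. The authors' deposited fold is the ratio of normalized reads MHC403 over WT; in the table it is blank where both libraries had under 10 reads and 999 where WT had 0. The authors' deposited p-value is given per gene, with a test that is not given in the sources used here. The authors' deposited start-site score is a whole number per gene, above 0 only in genes with at least 20 reads in both libraries, and its formula is not given in the sources used here.

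The table lists 680 entries with a position in the name, 804 entries that share their position with another entry, and 1418 measured entries (14.9%) whose windows overlap those of another entry, so some reads may be listed more than once. Symbols and coordinates were used as the table gives them, with starts written 1-based. The reference annotation at hand was of another build, so it was used only for names and for transcript sequence.

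Samples were grouped by the genotype label, 1 library each. Library totals were 5468677 reads in MHC403 and 5481123 in WT, and all columns of counts in the table belonged to these 2 libraries. With 1 pooled library per genotype there are no residual degrees of freedom, so no test across genotypes was made. The log2 ratio of reads scaled to library totals was computed instead, with an exact (Clopper-Pearson) 95% interval of the ratio conditional on the reads of the gene in both libraries. Genes were called measured with at least 50 reads in the higher library, and were listed as higher or lower at a 2-fold point estimate. At 50 reads in each library the interval runs from 0.662 to 1.51 around a ratio of 1. A library at 0 reads was set to a floor of 3 counts, per library, and the ratio given against this floor with the lower limit of the counting interval. Amplified reads carry no molecular identifiers in this table, so intervals do not include amplification, pooling or animal-to-animal variation.

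The test rules, 33 gene lists, named genes and most alternatives were chosen before the data were examined. Lists covered the fetal and hypertrophic programme, sarcomere, extracellular matrix, TGF-beta, oxidative phosphorylation, mitochondrially encoded transcripts, fatty acid oxidation, glycolysis, calcium handling, ion channels, calcineurin and NFAT, heat shock, immediate early genes, cell cycle, circadian clock, complement and major histocompatibility, interferon-stimulated genes, renin-angiotensin signalling, ribosomal proteins and sex-linked genes. Further lists held markers of macrophages, lymphocytes, endothelium, fibroblasts, smooth muscle, erythroid cells, atrial and ventricular myocytes, skeletal muscle, adipocytes, mesothelium, Schwann cells and neutrophils. For the 26 lists with at least 3 measured members, the median log2 ratio was given with its percentile among 10000 random lists of the same size drawn from the same 10 equal classes of mean expression. For lists with fewer than 3 measured members, reads of the entries under the minimum were summed, a step added after the values were seen. Intervals of list medians are binomial order-statistic intervals over genes and describe these libraries only.

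Named genes were the 12 higher and 12 lower entries whose counting interval had its nearer bound farthest from a ratio of 1, up to 4 members of each list by the same bound, and a fixed set. Some genes that this rule names are not reported here. The fixed set (Myh6, Myh7, Nppa, Nppb, Acta1, Actc1, Fhl1, Fhl2, Rcan1, Xirp2, Ankrd1, Atp2a2, Pln, Postn, Timp1, Ctgf, Tgfb2, Col1a1 and Col3a1) was drawn up from what is known of this disease model and study, so it is not an independent choice. Shares of reads per start site had been planned, with the 12 genes of largest share difference to be named, but the table holds 1 value per gene. The 12 genes with the highest deposited score were named in their place, a choice made after the table was seen. Myosin genes other than Myh6 and Myh7, Myl4, Myl7 and Xist were chosen after their values were seen.

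Alternatives were median-of-ratios scaling, computed directly, TMM factors from edgeR, other read minimums and fold rules, totals without mitochondrial and the 20 most abundant entries, and other treatment of entries sharing a symbol or position. For Myh7, every 36-base word of each myosin's longest coding transcript was looked up in the Myh6 transcripts of the GRCm38 annotation, exactly and with up to 2 mismatches. Words shared exactly between Hspa1a and Hspa1b and between C4a and C4b were counted the same way, with noncoding processed transcripts included, after the results were seen. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, used for TMM only.

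The ratio step was tested on simulated data drawn from the mean of the MHC403 and WT libraries and from their totals. Both simulated libraries had Poisson counting error only and a shared mean per gene, apart from the genes set to change. The simulation therefore checks the computation and gives no rate of false calls in the real libraries. It holds no amplification, pooling or animal-to-animal variation and no general shift in RNA composition. Over 8904 simulated measured genes, 95.5% of intervals held the true ratio. Of 8704 unchanged genes 5 passed the 2-fold rule. All of the 34 genes set 4-fold higher, the 34 set 4-fold lower, and the 33 set 3-fold in each direction passed it. Of genes set exactly at the 2-fold rule, 42.4% of the higher and 51.5% of the lower passed.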

Results

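The series measured transcript 5′ ends in mouse hearts by 5′RNA-seq, a polyA RNA-seq variant in which neither RNA nor cDNA is fragmented, so that reads gather near transcription start sites. There were 2 libraries, 1 from wild-type (WT) mice and 1 from MHC403/+ mice, a model of hypertrophic cardiomyopathy (HCM) caused by a missense mutation in the cardiac myosin heavy chain. Both genotypes were on the 129/SvEv strain, were 8 to 16 weeks old and had received CsA (cyclosporine A, an inhibitor of the phosphatase calcineurin) under the skin at 15 mg/kg, 2 injections a day for 2 weeks. Biological replicates had been pooled before sequencing, so each genotype had 1 library, no difference had a replicate check, and no p-value is given across genes. The MHC403 library held 5468677 reads and the WT library 5481123 over 30385 listed genes, totals that differed by 0.227%. Of these genes 16092 had reads in both libraries, and 9507 had at least 50 reads in the higher library and are called measured here. Ratios are MHC403 over WT after scaling to library totals, and the ranges after them are exact (Clopper-Pearson) 95% counting intervals. These intervals, and the floor of 3 counts used where a library had 0 reads, cover counting error only. Positions are on the mm9 build.

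The comparison asked which transcripts differed between hearts with and without the HCM genotype under the same drug treatment. Transcripts of natriuretic peptides and the extracellular matrix were far higher in the MHC403 library. Mitochondrially encoded transcripts and genes of fatty acid oxidation were lower, as were reads listed for the myosin heavy chain Myh6 and the ventricular light chain Myl2. Atrial natriuretic peptide, Nppa (chromosome 4, 147374855 to 147376176), was 30.8-fold (29.7 to 32.0) higher, with 92851 reads against 3017 in WT, which made up 1.70% of all MHC403 reads (exact 95% interval 1.69 to 1.71) and 0.0550% of WT reads (0.0531 to 0.0570). The alpha-myosin heavy chain gene Myh6 (chromosome 14, 55560758 to 55585444) was 2.40-fold (2.38 to 2.43) lower, with 55171 reads against 132965 in WT. The table counts reads per gene and not per allele, so these values do not check the genotype labels. Both pools came from CsA-treated mice and there was no untreated library, so the effect of the drug was not measured. A response to CsA that differs between the genotypes cannot be told apart from the genotype in these ratios.

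Of the 9507 measured genes, 2483 were at least 2-fold higher in the MHC403 library and 231 at least 2-fold lower, and 551 and 31 of them differed by at least 4-fold. This split depended on the scaling. The median log2 ratio of all measured genes was 0.57 (1.48-fold), and median-of-ratios scaling, which lowers every log2 ratio by 0.55, gave 1034 genes higher and 722 lower. The 1034 genes were all among the 2483, and the 231 were all among the 722. Of the genes named here, Ankrd1, Eno1, Hk1, Sri, Nfatc1, Nfatc2, Hbb-b1, Pam, Cidea, Ifitm3, Ube2d3, Myh9 and Myh10 were at least 2-fold higher with library totals and not with median-of-ratios scaling, and Atpase6, Fhl2, Pln and Tcea3 were at least 2-fold lower only with the latter. The share of higher genes among those past 2-fold was 91.5% with library totals and 58.9% with median-of-ratios scaling, so some list medians are also given below relative to the median of all measured genes. Across the 9501 genes with at least 50 reads in the higher library and reads in both, log2 RPM (reads scaled to the library total) had a Pearson correlation of 0.867 and a Spearman correlation of 0.842, and genes are not independent replicates.

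**Figure D1:**
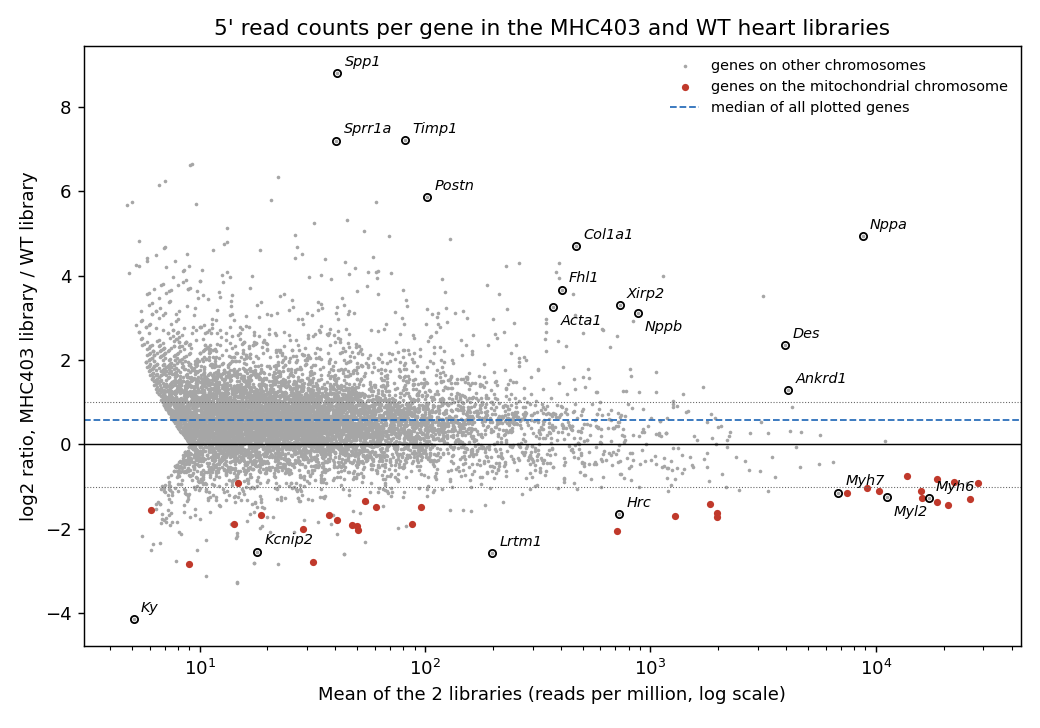
Log2 ratio of the MHC403 over the WT library against the mean of both libraries in RPM (log axis) for the 9507 measured genes, 1 point per gene. The median of all points, the dashed line, lies at 0.57, the mitochondrially encoded genes in red lie below 0, and Nppa lies at 4.95 among the most abundant transcripts; dotted lines mark a 2-fold ratio.

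Among the genes with the largest excess in the MHC403 library, Sprr1a (small proline-rich protein, chromosome 3, 92287876 to 92289803) had 442 reads against 0 in WT. It was 147-fold higher against the floor of 3 counts, with a lower limit of 119.6. Tnc (tenascin C, a matrix glycoprotein, chromosome 4, 63620819 to 63708049) had 243 against 0, 81.1-fold higher against the floor, with a lower limit of 65.5. Spp1 (osteopontin, chromosome 5, 104864130 to 104870072) had 446 reads against 1, a ratio of 447-fold (79.8 to 17695). Timp1 (a metalloproteinase inhibitor, chromosome X, 20447292 to 20451863) was 148-fold (67.7 to 404) higher and Postn (periostin, chromosome 3, 54165029 to 54194963) 58.2-fold (37.1 to 97.0) higher. Thbs1 (thrombospondin 1) was 54.1-fold (30.8 to 105) higher, Ltbp2 (a latent TGF-beta binding protein) 40.1-fold (22.7 to 78.1) and the hyaluronan receptor Cd44 33.5-fold (20.8 to 58.0). The gene listed as Itgb1bp3 and described in the file as nicotinamide riboside kinase 2 was 29.2-fold (21.8 to 40.0) higher, and Col1a1 (collagen type I alpha 1, chromosome 11, 94797584 to 94813170) 26.2-fold (22.6 to 30.5) higher, with 4914 reads against 188 in WT.

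Among the 12 names chosen for the largest deficit in the MHC403 library, Ky (kyphoscoliosis peptidase, chromosome 9, 102408468 to 102448569) had 3 reads against 53, 17.6-fold (5.71 to 88.2) lower. Mylk4 (a myosin light chain kinase) was 8.73-fold (4.79 to 17.4) lower, Asb14 7.08-fold (4.82 to 10.8) and Lrtm1 (chromosome 14, 29831394 to 29846828) 5.99-fold (5.31 to 6.78), the last with 311 reads against 1868 in WT. Pxmp2, which encodes a peroxisomal membrane protein, was 6.11-fold (4.71 to 8.03) lower, Ttll1 6.03-fold (4.66 to 7.91) and Dhrs7c 4.97-fold (4 to 6.23). The genes listed as 3110057O12Rik and Cdv1R were 9.71-fold (5.70 to 17.8) and 9.64-fold (5.66 to 17.7) lower. Fox1 and Rbfox1 are overlapping entries with the same 24 reads against 168, 6.98-fold (4.54 to 11.2) lower, and the entry mt-tRNA-Gly, 6.89-fold (5.01 to 9.69) lower, overlaps mt-Nd3, so reads within each pair cannot be assigned to 1 entry.

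Genes of the fetal and hypertrophic programme, which are re-expressed in stressed ventricles, stood far above the rest. Of 13 measured members 12 were at least 2-fold higher and 1, Myh7, was lower. Nppb (brain natriuretic peptide, chromosome 4, 147359898 to 147361314) was 8.69-fold (8.13 to 9.28) higher, skeletal alpha-actin Acta1 (chromosome 8, 126415667 to 126418636) 9.54-fold (8.59 to 10.6), the ubiquitin hydrolase Uchl1 30.5-fold (20.4 to 48.0) and the growth factor Ctgf (chromosome 10, 24315248 to 24318488) 11.9-fold (10.7 to 13.3). Fhl1, an X-linked LIM-domain protein of muscle (chromosome X, 53984964 to 54046523), was 12.7-fold (11.4 to 14.3) higher, with 4103 reads against 323 in WT, and the stress-responsive ankyrin repeat gene Ankrd1 (chromosome 19, 36186455 to 36194334) 2.43-fold (2.38 to 2.48) higher. The list median was 3.12, that is 2.55 above the median of all measured genes. It lay at percentile 100 among 10000 random lists of the same size matched on mean expression, and was 2.23 with a minimum of 20 reads. The members Nppa, Nppb, Myh7, Acta1, Ankrd1, Fhl1, Rcan1 and Ctgf are also in the fixed set drawn up from knowledge of this disease model. This percentile is therefore not independent of that knowledge. Myh7 (beta-myosin heavy chain, chromosome 14, 55589525 to 55613386) was 2.21-fold (2.17 to 2.24) lower, with 23161 reads against 51258 in WT. Myh7 shares 28.8% of its 36-base words with Myh6 transcripts, or 56.7% with up to 2 mismatches, though none in its first 200 bases, so the reads of both are uncertain, and the windows of Uchl1 and Ctgf overlap those of unnamed transcripts.

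Sarcomere and Z-disc genes lay on both sides of a ratio of 1. Of 28 measured genes 7 were at least 2-fold higher, 2 lower and 19 within 2-fold. The higher genes included the Z-disc and intercalated disc proteins Xirp2 (chromosome 2, 67032813 to 67364663; 9.90-fold, 9.18 to 10.7), Synpo2l (5.66-fold, 5.17 to 6.20), desmin, Des (5.09-fold, 4.96 to 5.22), and Ankrd23 (3.54-fold, 3.30 to 3.81). Myh6 and the ventricular light chain Myl2, 2.39-fold (2.36 to 2.42) lower, were the 2 lower genes, while cardiac actin Actc1 (chromosome 2, 113873025 to 113878547) was 1.85-fold (1.81 to 1.88) higher and within 2-fold. Fhl2 (chromosome 1, 43179919 to 43253606), a LIM-domain partner of sarcomeric proteins, was 1.71-fold (1.62 to 1.79) lower. The list median was 0.19 at percentile 8.56, and it lay at -0.35 with median-of-ratios scaling, where 4 genes were higher and 6 lower.

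Extracellular matrix genes were the group with the highest list median. Of 48 measured genes 43 were at least 2-fold higher, none was lower and 5 were within 2-fold. The fibrillar collagen Col3a1 (chromosome 1, 45368383 to 45406551) was 19.8-fold (17.2 to 22.9) higher, with 4088 reads against 207 in WT, and Col1a2 15.3-fold (13.5 to 17.4) higher. The list median of 3.15 (8.91-fold) lay 2.59 above the median of all measured genes, at percentile 100. In the list of TGF-beta ligands, receptors and targets 14 of 19 measured genes were at least 2-fold higher and none was lower, with a median of 1.39 at percentile 100. Tgfb2, a ligand (chromosome 1, 188447065 to 188529871), was 11.0-fold (7.93 to 15.7) higher, whereas 8 of the 19 passed 2-fold with median-of-ratios scaling. The TGF-beta list median was 2.28 with a minimum of 200 reads.

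Transcripts encoded on the mitochondrial chromosome took 13.7% of all MHC403 reads (exact 95% interval 13.6 to 13.7) and 29.5% of WT reads (29.5 to 29.6). The entry Atpase6, chosen after its values were seen, is described in the file as a mitochondrial gene but placed on chromosome 1, and it had 96549 reads against 182263 in WT; with it the shares were 15.4% and 32.9%. Of 31 measured mitochondrially encoded entries 27 were at least 2-fold lower and 4 within 2-fold, with a median of -1.48 at percentile 0. The ribosomal RNA mt-12SrRNA was 4.18-fold (3.95 to 4.43) lower, mt-tRNA-Ala 4.09-fold (3.31 to 5.10) and mt-tRNA-Ile 7.15-fold (3.89 to 14.4). Neighbouring mitochondrial entries overlap, and the strand use of the counting is not given in the sources used here, so single entries are uncertain. Nuclear genes of oxidative phosphorylation were lower by a smaller margin. Of 75 measured, 3 were at least 2-fold lower and 72 within 2-fold, with a median of -0.36 at percentile 0. The 3 were the complex I subunits Ndufa3, 2.15-fold (2.07 to 2.23) lower, and Ndufa5, 2.01-fold (1.92 to 2.09), and the complex IV subunit Cox7a1, 2.00-fold (1.95 to 2.06). In 68 of the 75 the counting interval lay wholly below a ratio of 1, and 25 were at least 2-fold lower with median-of-ratios scaling.

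Genes of fatty acid uptake and oxidation, the main fuel pathway of the adult heart, were lower. Of 30 measured genes 6 were at least 2-fold lower, none was higher and 24 were within 2-fold, with a median of -0.67 at percentile 0, that is 1.24 below the median of all measured genes. Hadhb, a subunit of the trifunctional protein, was 2.58-fold (2.36 to 2.82) lower, the thiolase Acaa2 2.26-fold (2.09 to 2.44), the dehydrogenase Hadh 2.09-fold (1.94 to 2.25) and the lipid-sensing receptor Ppara 2.5-fold (1.97 to 3.19). With median-of-ratios scaling 23 of the 30 were at least 2-fold lower. Among 20 measured genes of glycolysis and glucose uptake 4 were at least 2-fold higher and 1 lower with library totals, and 1 was higher and 4 lower with median-of-ratios scaling. Pfkp (platelet phosphofructokinase) was 6.66-fold (5.36 to 8.37) higher, Eno1 2.57-fold (2.28 to 2.90) and Hk1 2.30-fold (2.10 to 2.52), and Pfkfb2, which makes a phosphofructokinase activator, was 3.09-fold (2.55 to 3.78) lower. Their median of 0.60, at percentile 82.4, lay 0.03 above that of all measured genes, and Eno1 and Hk1 overlap other entries.

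Calcium-handling genes lay on both sides too. Of 19 measured, 2 were at least 2-fold higher, 2 lower and 15 within 2-fold. The sarcoplasmic reticulum calcium pump Atp2a2 (chromosome 5, 122903522 to 122952234) was 2.14-fold (2.09 to 2.19) lower, and Hrc, a calcium-binding protein of the same compartment, 3.15-fold (2.99 to 3.31) lower. Phospholamban, Pln (chromosome 10, 53057492 to 53065805), which inhibits the pump, was 1.95-fold (1.88 to 2.02) lower, within 2-fold. Casq1 was 4.83-fold (3.03 to 8.03) higher and sorcin, Sri, 2.43-fold (1.99 to 2.98) higher. The list median was 0.04 at percentile 2.30, which was 4.44 with a minimum of 200 reads, and the median became -0.50 with median-of-ratios and with TMM scaling. Median-of-ratios scaling left 1 of these genes higher and 3 lower. Among 18 measured ion channel and connexin genes 1 was at least 2-fold higher and 3 lower, or 1 and 6 with median-of-ratios scaling. Their median was -0.09 at percentile 0.04, which was 2.75, inside the central 95% of random lists, with a minimum of 200 reads. Kcnip2, a subunit of the transient outward potassium channel, was 5.81-fold (3.90 to 8.95) lower and the KATP channel subunit Abcc9 2.94-fold (2.61 to 3.32) lower.

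In the calcineurin and NFAT list 3 of 10 measured genes were at least 2-fold higher and none was lower, with a median of 0.70 at percentile 71.8. Rcan1 (chromosome 16, 92392198 to 92466391), a calcineurin regulator that is itself induced by NFAT, was 4.70-fold (3.95 to 5.64) higher. Its reads were counted over 2 annotated starts together, so the start that differed is not known. Nfatc1 was 2.42-fold (1.76 to 3.36) higher and Nfatc2 2.19-fold (1.64 to 2.95). With median-of-ratios scaling 1 gene of the list passed 2-fold. Immediate early genes, transcription factors and regulators induced within minutes of a stimulus, were higher in 14 of 17 measured cases and lower in none. Their median was 1.69 at percentile 100, and 10 of the 17 were at least 2-fold higher with median-of-ratios scaling. Egr1 was 15.2-fold (10.2 to 23.6) higher, Myc 10.7-fold (7.05 to 17.1) and Junb 8.6-fold (6.44 to 11.7). Egr2 had 57 reads against 0 in WT, 19.0-fold higher against the floor, with a lower limit of 15.0. Of 19 heat shock and unfolded protein response genes 8 were at least 2-fold higher and none lower, or 6 and none with median-of-ratios scaling. Their median was 0.62 at percentile 76.7, which was 99.1 with a minimum of 200 reads. The gene copies Hspa1a and Hspa1b, which share 62.3% and 66.0% of their 36-base words, were 16.9-fold (12.1 to 24.3) and 17.4-fold (12.5 to 24.9) higher. The small heat shock protein Hspb1 was 4.98-fold (4.68 to 5.30) higher, and the cochaperone Dnajb1 3.67-fold (2.72 to 5.02) higher. In the renin-angiotensin and natriuretic list 4 of 9 measured genes were at least 2-fold higher, with a median of 0.70 at percentile 79.7. They were angiotensin-converting enzyme, Ace (4.81-fold, 4.09 to 5.67), the endothelin receptor Ednrb (4.72-fold, 3.31 to 6.89), and Nppa and Nppb, which are also in the fetal list. This renin-angiotensin median depended on the read minimum, at 0.50 and percentile 44.7 with 20 reads and 2.69 and percentile 99.9 with 200.

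Markers of non-myocyte cells differed in size by cell type. Of 20 measured macrophage markers 18 were at least 2-fold higher and none was lower, or 14 and none with median-of-ratios scaling. Their median was 1.70 at percentile 100. The lectin Lgals3 was 25.9-fold (14.2 to 52.4) higher, the protease Ctss 8.94-fold (6.68 to 12.2) and Cd68 5.55-fold (4.02 to 7.80). Of 18 fibroblast markers 11 were at least 2-fold higher, 7 within 2-fold and none lower, with a median of 1.47 at percentile 100. With median-of-ratios scaling 8 of the 18 were higher and none lower. S100a4 was 16.7-fold (12.3 to 23.2) higher and Mfap5 21.9-fold (15.0 to 33.3), while Dcn was 1.79-fold (1.69 to 1.90) higher, within 2-fold. Of the 18 markers, 6 are also in the matrix list, Mfap5 and Dcn among them. Of 20 endothelial markers 2, Cldn5 (3.30-fold, 2.45 to 4.51) and Ecscr (2.98-fold, 2.09 to 4.34), were at least 2-fold higher and 18 within 2-fold. The endothelial median was 0.39 at percentile 20.9 and lay at -0.16 with median-of-ratios scaling, where 2 markers were higher and 2 lower. Of 13 smooth muscle and pericyte markers 6 were at least 2-fold higher, with a median of 0.88 at percentile 96.0, which was 99.1 with a minimum of 200 reads. Among the 6 were Cspg4 (4.51-fold, 3.50 to 5.88), Myl9 (3.79-fold, 3.13 to 4.62), Acta2 (2.94-fold, 2.54 to 3.43) and Des, which is also in the sarcomere list. The smooth muscle myosin Myh11 was at 1.03-fold (0.827 to 1.29). Erythroid transcripts, which reflect blood in the tissue, had a median of 0.94 at percentile 90.1 over 4 entries, with Hba-a2 1.64-fold (1.59 to 1.69) higher and Hbb-b1 2.19-fold (1.98 to 2.42) higher.

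Genes of the ventricular myocyte list were lower in 3 of 8 measured cases and higher in none, with a median of -0.69 at percentile 0.02. The 3 were Kcnip2, Myh6 and Myl2, and 5 were lower with median-of-ratios scaling. Of the 8, 4 are also in the sarcomere list, Myh6 and Myl2 among them. A further 2, Gja1 and Kcnip2, are also in the ion channel list, so this result is not independent of those lists. Of 5 measured atrial markers 3 were at least 2-fold higher, namely Nppa, Dkk3 (13.2-fold, 6.14 to 33.7) and Pam (2.37-fold, 2.24 to 2.5), or 2 higher and 1 lower with median-of-ratios scaling. The atrial median of 1.24 at percentile 95.1 was 0.20 at percentile 9.59 with a minimum of 20 reads. The atrial light chains Myl7 and Myl4, chosen after their values were seen, had 31 and 24 reads in MHC403 against 27 and 19 in WT, too few to be measured. Lymphocyte and Schwann cell lists had 0 measured members, and 4 lists had 1 each: Cidea for adipocytes (2.13-fold, 1.66 to 2.74), Krt18 for mesothelium (15.6-fold, 6.42 to 49.5), S100a9 for neutrophils (12.4-fold, 5.42 to 34.8) and Pcna for the cell cycle (1.34-fold, 1.10 to 1.62), all as MHC403 over WT, with Pcna at a log2 ratio of -0.13 after median-of-ratios scaling. Pcna does not stand for its list: the 19 other cell-cycle entries, each under 50 reads, had together 277 reads against 65 in WT, 4.27-fold (3.25 to 5.69) higher, a sum added after the values were seen, at a log2 ratio of 1.55 with median-of-ratios scaling. The same sums were 2.51-fold (1.25 to 5.37) higher for lymphocytes, 2.27-fold (1.70 to 3.07) for mesothelium, 6.01-fold (2.31 to 19.9) for neutrophils, 1.42-fold (1.02 to 1.98) for Schwann cells and 1.40-fold (0.763 to 2.63) for adipocytes. With median-of-ratios scaling their log2 ratios were 0.78, 0.64, 2.04, -0.04 and -0.06 in the same order, so the Schwann cell and adipocyte sums were no longer higher. Cytosolic ribosomal protein genes had 77 of 81 measured members within 2-fold and a median of 0.55 at percentile 93.8, which was 0.00 with median-of-ratios scaling. Within this list Rpl3 was 5.13-fold (4.56 to 5.78) higher and its muscle paralog Rpl3l 2.93-fold (2.62 to 3.29) lower. The Y-linked genes Ddx3y and Eif2s3y had 123 and 149 reads in MHC403 against 84 and 128 in WT, and Xist, expressed from the inactive X chromosome of females, had 4 against 7.

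**Figure D2:**
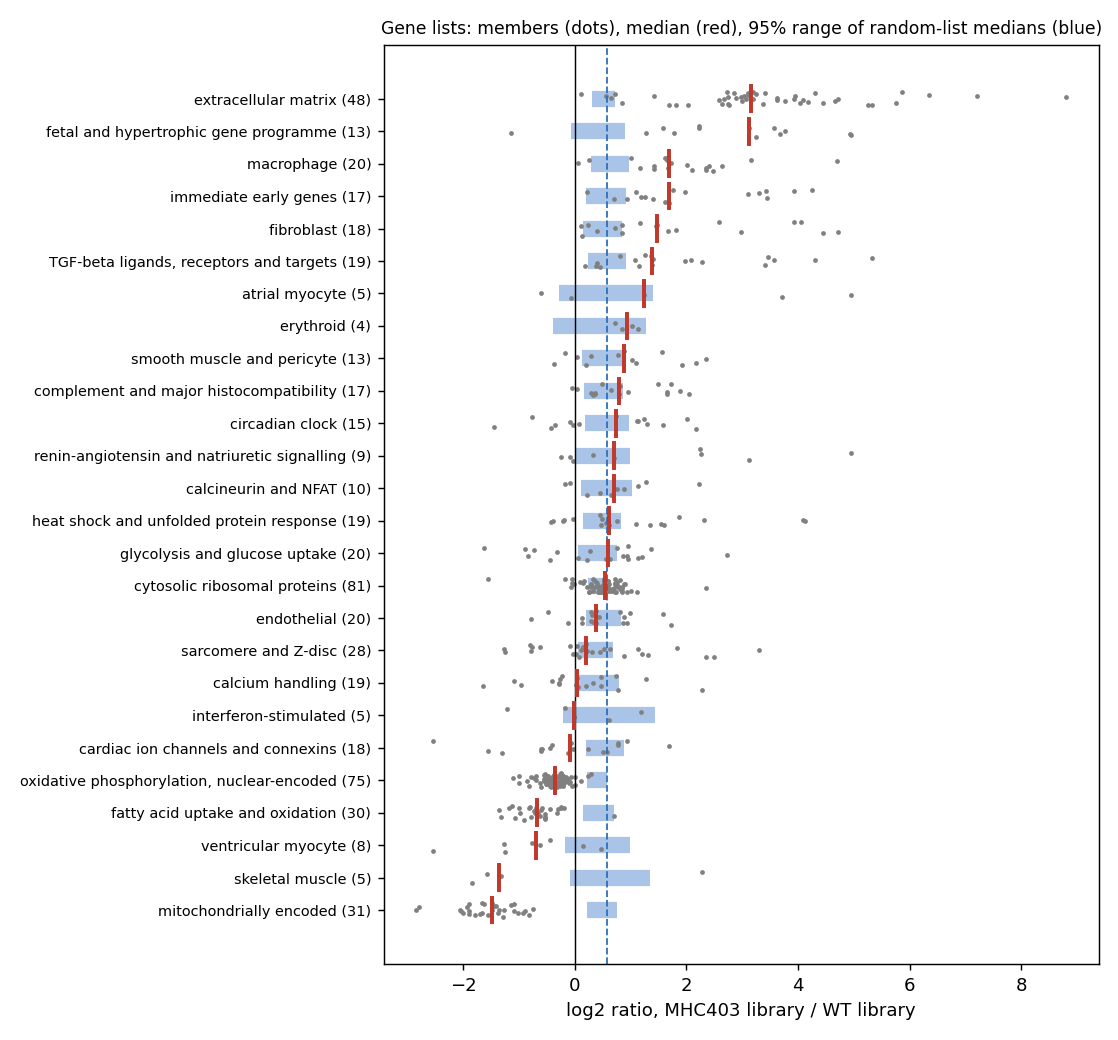
Log2 ratio of the MHC403 over the WT library for the measured members of the 26 gene lists with at least 3 of them (grey dots, number measured in brackets), with the list median as a red bar and the central 95% of medians of 10000 random lists matched on mean expression as a blue band. The dashed line is the median of all measured genes at 0.57, above which the matrix list reaches 3.15; with median-of-ratios scaling every value lies 0.55 lower, which puts the sarcomere, calcium-handling and endothelial medians below 0.

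The assay was also meant to detect genes whose start sites are used differently. The authors' deposited table gives each gene 1 start-site score, whose formula is not given in the sources used here, and no reads per start site, so shares of reads per site were not compared. Of the 10483 genes with at least 20 reads in both libraries, 3641 (34.7%) had a score above 0 in the authors' deposited table. A score above 0 was given to 31.7% of the genes with 1 annotated start (exact 95% interval 30.6 to 32.8) and to 40.1% of those with 2 or more (38.5 to 41.7), as the authors' deposited table lists them. Synpo2l (chromosome 14, 21478640 to 21487528, 3 annotated starts) had the highest score in the authors' deposited table, 293, followed by Fhl1 with 257 and 4 annotated starts. In the authors' deposited table Schip1 scored 151, Fhl2 148, Ube2d3 146, the matrix proteoglycan gene Dcn 144, Slc27a1 104, Tcea3 102, Atxn10 99, Flnc 97, 2210404J11Rik 94 and Nppa 93. Of the 96 measured genes with a score of 50 or more in the authors' deposited table, 30 were at least 2-fold higher, 6 lower and 60 within 2-fold. Schip1 (log2 ratio -0.26), Slc27a1 (-0.25) and 2210404J11Rik (0.08) were thus high in score with ratios near 1. The authors' deposited table also gives a p-value per gene, at or below 0.05 for 8848 of the 13955 genes with a fold, of which 3827 had a fold of at least 2 and 444 a fold of at most 0.5. The test behind this p-value is not given in the sources used here. With 1 pooled library per genotype, the p-value compares these 2 libraries and not the genotypes.

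**Figure D3:**
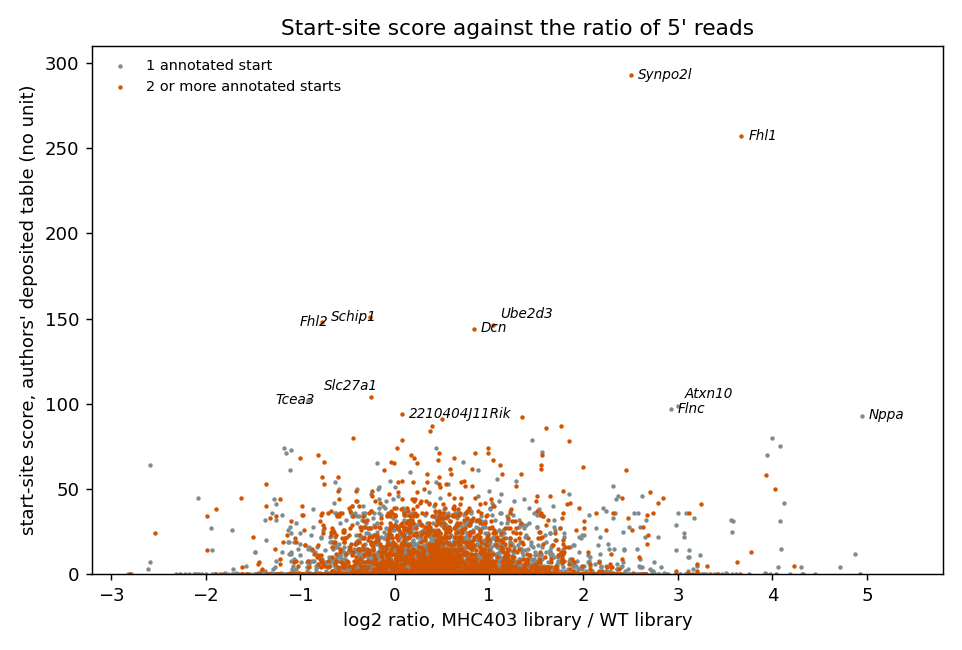
Start-site score from the authors' deposited table, which has no unit, against the log2 ratio of the MHC403 over the WT library for genes with at least 20 reads in both libraries, 1 point per gene, coloured by the number of annotated starts. Synpo2l at 293 and Fhl1 at 257 lie above all others, and genes with scores of 50 or more are spread over both sides of a ratio of 1.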

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

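The settings without mitochondrial entries alone, without these and Atpase6, with 1 entry per position and without overlapping windows were chosen after seeing the data. The counts of genes higher and lower in the MHC403 library, 2483 and 231 with library totals, were 1034 and 722 with median-of-ratios scaling, 1040 and 718 with TMM, 1528 and 400 without mitochondrial entries in the totals, 1449 and 429 without these and Atpase6, and 1309 and 504 without mitochondrial and the 20 most abundant entries. The median of all measured genes, 0.57, was 0.0218 with median-of-ratios scaling, 0.0240 with TMM, 0.28 without mitochondrial entries, 0.24 without these and Atpase6, and 0.18 without mitochondrial and the 20 most abundant entries. These differences follow from the scaling itself, which subtracts 1 value from every log2 ratio. With no read minimum the counts were 4799 and 723, with a minimum of 200 reads 989 and 100, and at 1.5-fold 4666 and 534, since these rules admit more or fewer genes. A counting interval wholly beyond 1.5-fold, summed entries per symbol, the most abundant entry per symbol, 1 entry per position and entries without overlapping windows each kept both counts within 1.5 times the main ones.

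With median-of-ratios scaling, and with TMM after each comma, list medians were -0.50, -0.50 for calcium handling, which is 0.04 with library totals and so reversed in sign. In the same order they were -0.35, -0.35 for sarcomere, 2.61, 2.61 for matrix, -0.91, -0.90 for oxidative phosphorylation, -1.22, -1.22 for fatty acid oxidation, -0.64, -0.64 for ion channels, 1.14, 1.14 for immediate early genes, 0.24, 0.24 for complement, 0.00153, 0.00372 for ribosomal proteins, -2.03, -2.03 for mitochondrially encoded, 1.15, 1.15 for macrophage, -0.16, -0.16 for endothelial, 0.39, 0.40 for erythroid and -1.90, -1.90 for skeletal muscle lists. The other 12 list medians moved by less than their interval under each. A minimum of 200 reads gave percentiles of 4.44 for calcium handling and 2.75 for ion channels, now inside the central 95% of random lists, and 99.1 for heat shock, 99.9 for renin-angiotensin, 98.3 for ribosomal and 99.1 for smooth muscle lists, now outside it. Without matching on expression the sarcomere list was at 0.41, outside it. For these percentiles the cause was not tested. With a minimum of 20 reads all 52 list medians and percentiles stayed within their interval or on their side of that range, but the fetal median went from 3.12 to 2.23, the atrial from 1.24 to 0.20 (percentile 95.1 to 9.59) and the skeletal muscle from -1.36 to -0.37. Of 19 genes named in advance, none reversed in sign, and 17 moved beyond their counting interval with median-of-ratios scaling, 17 with TMM and 16 with totals without mitochondrial and abundant entries.

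No paired analysis was possible because each genotype had 1 pooled library, and leaving out a replicate was not possible for the same reason. The alternatives on start-site shares were not run because the table has no reads per site, and those on the pseudocount were not run because it holds counts. Depth limits genes near 50 reads, where a ratio between 0.662 and 1.51 is within counting error.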

Other observations

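The tests of mitochondrial reads and of cell-type and fibroblast shares, and the first-bases and mismatch checks for Myh7, were chosen after the results were seen; the tests of the 20 most abundant entries and of shared myosin sequence were not.

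The 7 measured sarcomeric myosins other than Myh6 and Myh7 were also lower in the MHC403 library, from 2.16-fold for Myh3 to 3.96-fold for Myh7b. Myh7b, a slow-type myosin of muscle, had 168 reads against 666 in WT. The nonmuscle myosins were higher, Myh9 by 2.66-fold (2.42 to 2.92), Myh10 by 2.42-fold (2.00 to 2.96) and Myh14 by 1.77-fold (1.60 to 1.97), while smooth muscle Myh11 had 166 reads against 161 in WT. The skeletal muscle list, with Myh1 (3.59-fold, 2.79 to 4.66 lower), Myh4 (2.97-fold, 2.43 to 3.65 lower) and Myh2 (2.51-fold, 1.90 to 3.34 lower), had 4 of 5 measured genes lower, 1 higher, and a median of -1.36 at percentile 0, which was -0.37 at percentile 0.16 with a minimum of 20 reads. The 7 sarcomeric myosins share from 1.66% of their 36-base words for Myh7b to 5.32% for Myh8 with Myh6 within 2 mismatches, none in the first 200 bases, and Myh6 had 132965 reads in WT, so a contribution of Myh6 reads to them is not excluded. Myh2 and Myh8 have overlapping windows and cannot be separated.

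Circadian clock genes differed in both directions. Of 15 measured, 7 were at least 2-fold higher and 1 lower with library totals, and 3 higher and 2 lower with median-of-ratios scaling. With library totals the list had a median of 0.73 at percentile 79.4. The clock repressors Bhlhe40, Per1 and Per2 were 4.52-fold (3.90 to 5.25), 4.02-fold (3.53 to 4.59) and 3.01-fold (2.31 to 3.96) higher, and Hlf, an output transcription factor, was 2.74-fold (1.86 to 4.14) lower. The hour at which hearts were taken is not given in the sources used here. In the complement and major histocompatibility list 6 of 17 genes were at least 2-fold higher and none lower, with a median of 0.79 at percentile 93.1. Complement C1qa was 3.29-fold (2.86 to 3.81) higher and C1qb 3.15-fold (2.78 to 3.59), both also macrophage markers, and C4b and C4a, which share 44.8% and 44.9% of their 36-base words, 3.69-fold (2.86 to 4.82) and 4.11-fold (2.88 to 6). Of 5 measured interferon-stimulated genes Ifitm3 was 2.27-fold (2.04 to 2.53) higher, and the list had a median of -0.02 at percentile 5.75.

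More genes were at least 2-fold higher than lower in the MHC403 library. If the smaller mitochondrial share were the whole cause, leaving these entries out of both totals would bring the median log2 ratio within 0.1 of 0; it went from 0.57 to 0.28, and to 0.24 without Atpase6 as well, so this explanation accounts for part and not all of the asymmetry. Leaving out the 20 most abundant entries as well gave 0.18, which again left a remainder. A shift spread over more of the abundant transcripts, in RNA composition or in library preparation, may account for the rest and remains open, as does the genotype, since 1 library per genotype confounds them. Of 10 equal classes of genes by mean expression, the highest had a median of 0.41, classes 2 to 9 had medians between 0.51 and 0.59, while the lowest, at 1.03 (0.98 to 1.08) with 499 genes higher and 52 lower, tells little because the minimum of 50 reads in the higher library admits mainly unequal reads there.

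Myh7, often raised in hypertrophied mouse ventricles, was listed as lower together with Myh6. A candidate explanation is reads shared with Myh6: 28.8% of the 36-base words of Myh7 occur in Myh6, or 56.7% with up to 2 mismatches, above the 20 percent set in advance for this explanation. That mark was too weak, because none of the 165 words in the first 200 bases, where most 5′ reads would lie, occurs in Myh6, even with 2 mismatches. The table does not split reads between the windows of Myh7, so shared reads at its other window cannot be told apart from Myh7 reads. Lower Myh7 expression with the genotype remains open as well. Myh7 and Myh6 were lower by similar factors, 2.21-fold (2.17 to 2.24) and 2.40-fold (2.38 to 2.43). Shared reads could give similar factors, and so could lower expression of both genes, so these values do not decide between them.

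Matrix, fibroblast and macrophage genes were higher in the MHC403 library. The explanation tested was a smaller share of cardiomyocytes that raised all other cell types alike. The endothelial median had an upper bound of 0.86, below the lower bounds of 2.86 for the matrix and 1.42 for the macrophage list. These bounds are over genes of 2 libraries and argue only against an equal rise for these lists. A smaller cardiomyocyte share with an uneven rise of other cells was not tested and remains open. The fibroblast list had a lower bound of 0.72, under that endothelial bound, so for this list an equal rise cannot be told apart from a change in fibroblasts. More fibroblasts with an unchanged amount of each transcript would raise markers and matrix genes alike if fibroblasts alone made both. The 12 fibroblast markers outside the matrix list had a median of 1.31 (0.39 to 2.59). The 42 matrix genes outside the fibroblast list had a median of 3.15 (2.90 to 3.63). Heart RNA does not show which cells made these transcripts, so the unequal medians cannot decide on more fibroblasts, which remain open. Higher matrix transcript levels per cell and more macrophages were not tested and remain open.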
